A study of Caenorhabditis elegans with 4 samples.

How the data were processed

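The series holds 4 libraries from Caenorhabditis elegans. In 3 of them nucleosomes carrying trimethylated histone H3 lysine 9 (H3K9me3), a mark of silent chromatin, were immunoprecipitated after micrococcal nuclease digestion of adult worms fed double-stranded RNA against smg-1. The strains were nrde-3(gg066), nrde-4(gg129) and glp-4(bn2). The other library holds small RNAs that came down with FLAG-tagged HRDE-1 by its title and strain, while its antibody label names NRDE-2; the title was followed, and every HRDE-1 value rests on that. Each group was 1 library, so every comparison is between libraries, with no replicate check, and no test across conditions was run. No input, wild-type or no-RNAi library was used here.

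Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The genome build is not given in the sources used here. Each deposited ChIP file lists every distinct position and strand at which a read of 25 nt starts, drawn out by the authors to a nucleosome-length fragment, with the count of reads that have that sequence. The score in the deposited files is a display shade set from that count, and it was not used. The display colour separates sequences with 1 place in the genome from sequences with several places. This meaning is inferred from the values. The colour was the same at 100% of the 3573680 positions and strands shared by the nrde-3 and nrde-4 libraries. In a check run after the results were seen, it was that of 1 place at 100% of the 99671 nrde-3 positions that hold a whole small RNA read with 1 place, against 49.7% of all nrde-3 positions. A read with several places is listed at each of them with its full count, so sums over all lines count it many times. For that reason the main values use reads with 1 place. The design had named all listed reads as the main setting, and this was changed once the files had been seen; all listed reads are given as an alternative. The deposited small RNA file lists 1 read per line and only reads with 1 place, per the file headers. ChIP listings of chromosome I stop at 15060000, and windows beyond that point were left out of the ChIP comparisons.

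Reads were placed at the nucleosome centre by a shift of 73 bp from the 5′ end and scaled to a library of 1000000 reads with 1 place (RPM). Counts carry exact Poisson 95% intervals, ratios exact conditional binomial 95% intervals and shares Wilson 95% intervals. These intervals cover counting error only, since reads from PCR are not independent molecules. Because the glp-4 library holds many copies of few molecules, values were also computed with each distinct position counted once. The RNAi target named in the labels is the interval from 6907993 to 6909159 of chromosome I. Flanks were the 5 kb on either side of it without the 200 bp next to it. They were set against all intervals of the same shape at steps of 1 kb over the 6 chromosomes that lay over 20 kb from smg-1 and had 50 or more reads in both libraries together. Windows of 1 kb with 50 or more reads in both libraries together were called different at a ratio of 2 or more, beside the number that random reassignment of the pooled reads by library size gives. That reassignment treats every read as independent. Arms were the outer 30% at each end of a chromosome and centres the middle 40%. A pseudocount of 0.5 reads was added for log2 ratios of single windows. Intervals of medians over windows are order-statistic 95% intervals and describe the spread of windows, which are not replicates.

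The rule for naming was set for genes before the data were examined, and it was applied to windows once the files had been seen. It takes the 10 highest and 10 lowest log2 ratios of each strain pair among windows with 100 or more reads in both libraries together. No annotation of the build of the files was used here, so windows stand in for genes, gene lists were not applied, sense and antisense to genes were not separated, and the first base of small RNAs was not read. The refseq table of WBcel235, whose coordinates differ from those of the files on chromosome IV, served only to name the neighbours of smg-1. For the 500 windows with the most HRDE-1 small RNAs, the median log2 ratio was placed among 10000 random lists of the same size drawn from the other windows in 20 bins of H3K9me3 density. Windows next to a named window were joined to it while 20 or more distinct positions in both libraries together gave a ratio of 2 or more in the same direction. This joining, the reach of the smg-1 block in 500 bp windows, the classes of windows by HRDE-1 reads and the windows higher in nrde-3 than in both other strains were not in the design and were set after the data had been seen. The reach was first counted from the border of the target itself, which gave 0 kb on the left since nucleosome centres of nrde-4 reads fall just outside it, and was then counted from 200 bp outside. For distinct positions in HRDE-1 windows a floor of 20 was used first; it was replaced by the floor of 50 of the main setting after its values had been seen, and both are given.

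The counting of windows was tested on simulated libraries with 200 changed windows per fold size. For nrde-3 over nrde-4, with 47666 simulated windows passing the floor, 99% of windows changed 3-fold and 7.04% of those changed 1.5-fold were called, against 0.442% of unchanged windows. For glp-4 over nrde-4, with 61920 windows, 98.5% of windows changed 3-fold and 0.434% of unchanged windows were called. For nrde-3 over glp-4, with 57966 windows, the values were 100% and 0.331%. The simulation drew every read independently, so these shares cover counting error only. They leave out copies of the same molecule and so do not describe the glp-4 library, with 7.66 reads per position. The alternatives were distinct positions, scaling by the median ratio of windows, placement at the 5′ end, other flank, window, floor, arm and list sizes, and all listed reads. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.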

Results

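Worms of 3 mutant strains had been fed smg-1 double-stranded RNA, and H3K9me3 nucleosomes of adults were sequenced from 1 library per strain. NRDE-3 is an Argonaute that carries small RNAs into somatic nuclei, so nuclear RNAi in nrde-3 mutants is left to the germline. NRDE-4 is needed for nuclear RNAi, and glp-4(bn2) worms lack most of the germline at restrictive temperature. HRDE-1 is the nuclear Argonaute of the germline. The comparisons ask whether H3K9me3 at an RNAi target and elsewhere depends on NRDE-4 and on the germline, and where HRDE-1 small RNAs come from. The nrde-3 library held 9597994 reads with 1 place at 5260345 distinct positions. The nrde-4 library held 5589483 reads at 2602173 positions, and the glp-4 library held 9053436 reads at 1182382 positions. These are 1.82, 2.15 and 7.66 reads per position, so the glp-4 library rests on the fewest molecules. The HRDE-1 library held 8291655 small RNA reads at 329799 distinct combinations of position, strand and length. The file headers give 16 °C for the nrde-4 worms and 23 °C for the glp-4 worms, and no temperature for the nrde-3 worms. They also place the nrde-4 library in another library series than the other 2. Library series and strain therefore cannot be told apart in comparisons with nrde-4, though nrde-3 and glp-4 share a series, and the part of growth temperature is open in all of them.

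The smg-1 gene encodes a kinase of nonsense-mediated mRNA decay, and its RNAi target spans 6907993 to 6909159 of chromosome I. Within that target the nrde-4 library had by far the most H3K9me3 ChIP reads, and the signal stopped at the target's borders. It held 893 RPM (reads scaled to a library of 1000000 reads; 868 to 918; 4991 reads), against 38.9 (35.0 to 43.01; 373 reads) in nrde-3 and 33.1 (29.5 to 37.1; 300 reads) in glp-4. The nrde-4 level was 22.98 times that of nrde-3 (20.7 to 25.6) and 26.9 times that of glp-4 (23.98 to 30.4). Counted as distinct positions, the excess was 7.08-fold over nrde-3 (6.15 to 8.16) and 12.0-fold over glp-4 (8.51 to 17.4). Only a limited number of positions fits in a target of 1.167 kb, and nrde-4 held 896. The lower ratios by distinct positions therefore cannot be put down to copies alone. Density in the target over density in the flanks was 360-fold in nrde-4 (299 to 438), 7.13-fold in glp-4 (6.09 to 8.35) and 2.96-fold in nrde-3 (2.63 to 3.34). Only 1 nrde-4 read crossed a border of the target, where the 100 bp inside the borders would give 205. In nrde-3, 8 reads crossed where 11.5 would be given.

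In the 5 kb flanks together nrde-4 was the lowest of the 3 strains. The nrde-3 library had a broad block of H3K9me3 on both sides of the target, while the nrde-4 library was below its own genome-wide median there. Flanks held 108 RPM in nrde-3 (101 to 115; 1035 reads), 20.4 in nrde-4 (16.8 to 24.5; 114 reads) and 38.2 in glp-4 (34.3 to 42.5; 346 reads). Per kb, this was 5.13 times the median 1 kb window of the nrde-3 library, 0.475 times that of nrde-4 and 0.948 times that of glp-4. The surroundings were below the median in each library: from 5 to 10 kb outside the target the values were 0.638, 0.516 and 0.55. The nrde-3 flanks were 5.29 times those of nrde-4 (4.35 to 6.47) and 2.82 times those of glp-4 (2.496 to 3.20). With distinct positions these ratios were 6.30 (4.86 to 8.30) and 4.55 (3.30 to 6.45). Among 99603 intervals of the same shape, 30 had as high a ratio of nrde-3 over nrde-4, and with distinct positions 1 of 99538 did. For nrde-3 over glp-4, 880 of 99634 had as high a ratio, and with distinct positions 213 of 99451 did. The glp-4 flanks were 1.87 times those of nrde-4 by reads (1.51 to 2.34) and 1.38 times by distinct positions (0.903 to 2.10), and the sides differed. On the right glp-4 was 4.30 times nrde-4 (2.98 to 6.40; distinct positions 2.62, 1.41 to 4.92), and on the left 0.884 times (0.660 to 1.19; distinct positions 0.751, 0.378 to 1.41).

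The nrde-3 block fell away with distance. From 200 bp to 1 kb outside the target nrde-3 exceeded nrde-4 by 9.38-fold (5.97 to 15.6), from 1 to 2 kb by 5.77-fold (3.95 to 8.70) and from 2 to 5 kb by 3.79-fold (2.90 to 5.01). From 5 to 10 kb the ratio was 0.605 (0.471 to 0.776), near the 0.558 of the median interval of the flank shape across the genome, and by distinct positions it was 0.812 (0.594 to 1.12). In 500 bp windows of distinct positions, a ratio of 2 or more ran without a break for 3.7 kb to the left and 4.7 kb to the right, from 6904293 to 6913859 on chromosome I. The reach depends on where the windows start: over 10 starts it was 2.3 to 5.75 kb on the left and 4.35 to 4.8 kb on the right. In glp-4 the right flank held 230 reads at 25 positions and the left flank 116 reads at 14 positions. The protein-coding genes next to smg-1 are srb-15, of a chemoreceptor family, and haps-1; which part of the block lies over them was not determined.

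**Figure D1:**
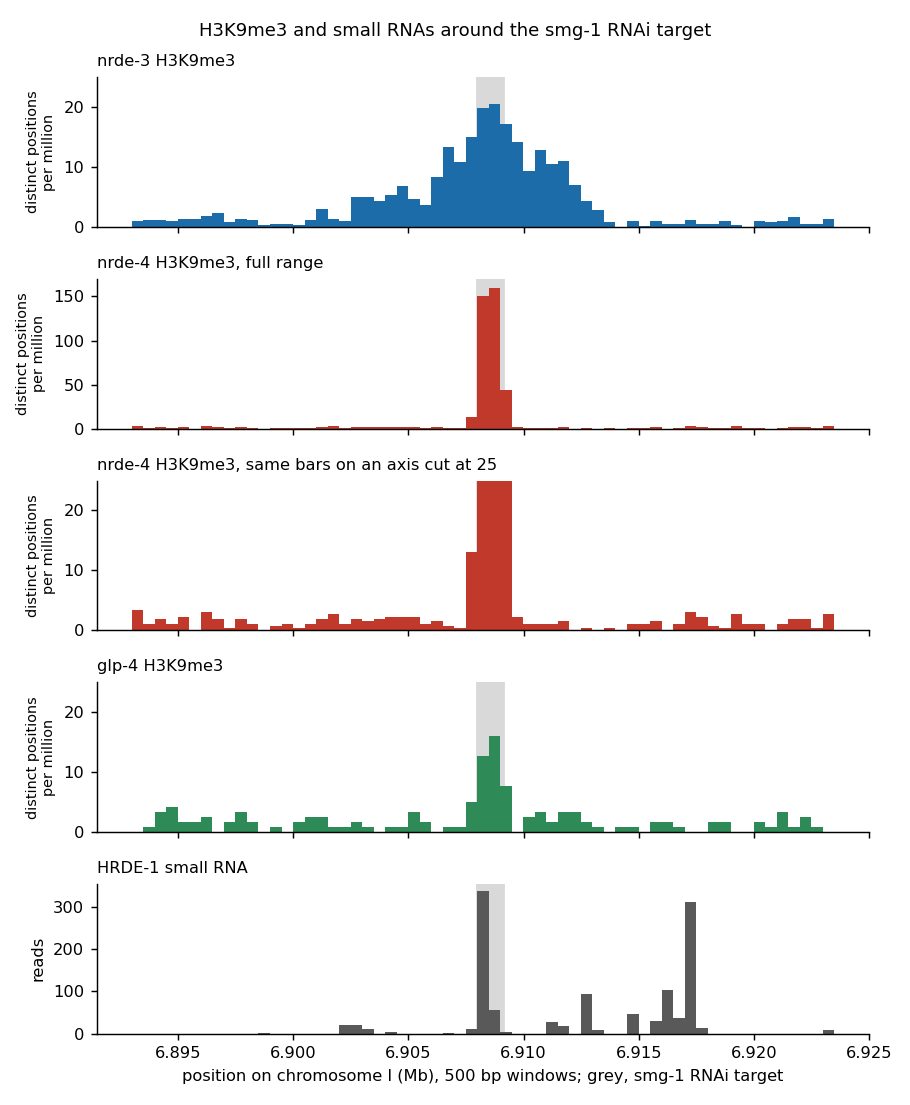
Distinct H3K9me3 positions scaled to 1000000 in 500 bp windows (bars) over 15 kb to either side of the start of the smg-1 RNAi target (grey) on chromosome I, for the nrde-3, nrde-4 and glp-4 libraries, with HRDE-1 small RNA reads at the bottom; nrde-4 is drawn at full range and again with its axis cut. The nrde-3 signal spreads beyond the target, and the nrde-4 signal stays within about 1 window of it.

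H3K9me3 lay mainly on the chromosome arms in all 3 libraries, and most steeply in nrde-3. Density on arms over centres was 6.54 in nrde-3, 3.86 in glp-4 and 3.27 in nrde-4. Chromosome V had the steepest contrast, 11.5 in nrde-3, 5.80 in glp-4 and 4.76 in nrde-4, and chromosome X the shallowest, 3.26, 2.26 and 2.06. Chromosome V also took the largest share of reads, 38.4% in nrde-3, 31.95% in glp-4 and 29.5% in nrde-4. Centres held 2.31 RPM per kb in nrde-3, 3.67 in glp-4 and 4.22 in nrde-4. With distinct positions the arm contrast was 4.64, 3.67 and 2.96, in the same order of strains. With all listed reads, most of them from repeated sequence, it was 1.82 in nrde-3, 1.77 in glp-4 and 1.72 in nrde-4.

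**Figure D2:**
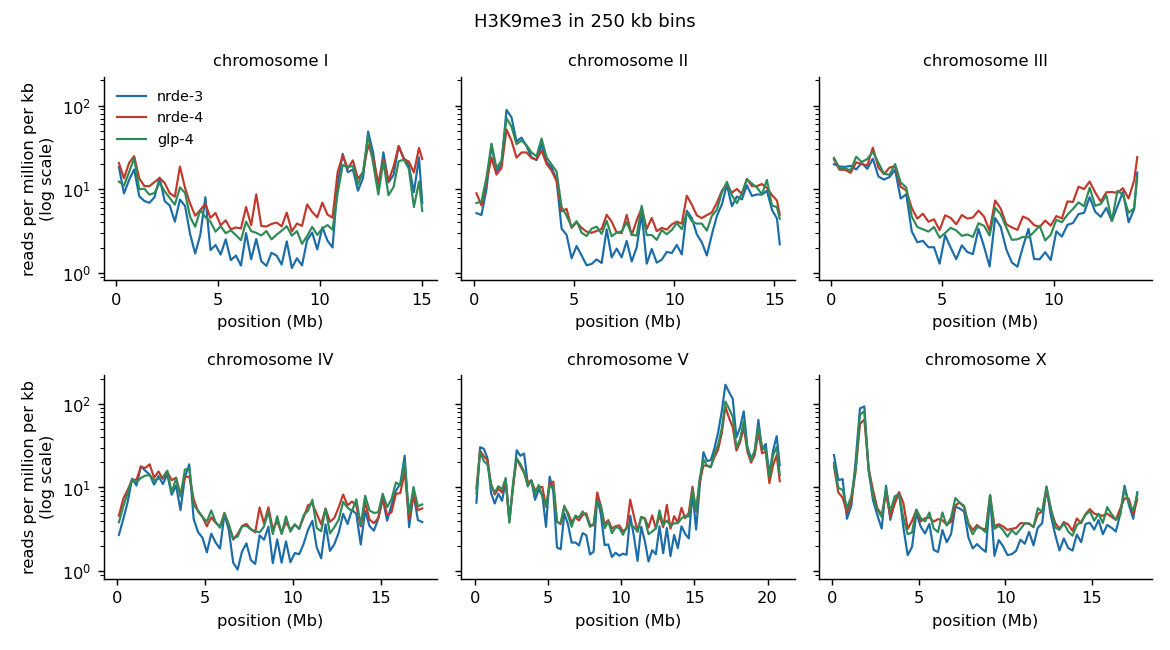
H3K9me3 RPM per kb (log scale) in bins of 250 kb along the 6 chromosomes; each line is 1 library. Arms lie above centres in the 3 libraries, and over centres the nrde-3 mean, 2.31 RPM per kb, is the lowest of the 3.

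Across the genome, 2319 of 47386 windows of 1 kb were at least 2-fold higher in nrde-3 than in nrde-4 and 12024 were lower, where random reassignment of reads gives 165 and 56. Of the lower windows 31.9% lay on chromosome centres, against 10.4% of the higher and 18.4% of all tested; by distinct positions the shares were 19.9%, 16.1% and 11.3%. The median ratio of windows was displaced by -0.40 on the log2 scale, and relative to it 5926 windows were higher and 6507 lower. With distinct positions, 1773 of 34051 windows were higher and 1977 lower. For glp-4 over nrde-4, 9109 of 62030 windows were higher and 8467 lower by reads, a displacement of 0.13, or 7266 and 9940 relative to it, but 707 and 2166 of 18890 by distinct positions. For nrde-3 over glp-4, 4353 of 58004 were higher and 20870 lower by reads, a displacement of -0.58, which became 10684 and 11551 relative to it, and 3635 and 689 of 28080 by distinct positions. With distinct positions the floor of 50 applies to positions, so fewer windows were tested and these counts differ from those by reads in both respects.

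Most of the windows with the highest ratio of nrde-3 over nrde-4 fell in short domains that also gave rise to HRDE-1 small RNAs. Of the 10 highest windows, 8 held 100 or more HRDE-1 reads, against 1 of the 10 lowest, which was the smg-1 target itself. Among all windows tested for this pair, 9.84% did. Windows were ranked by log2 ratios with the pseudocount added, and the ratios given here are without it. The highest window by that ranking was 12745001 to 12746000 on chromosome II. It had 990 reads in nrde-3 and 26 in nrde-4, a ratio of 22.2 (15.0 to 34.1). It belongs to a domain of 11 kb, 12740001 to 12751000, with 638 RPM in nrde-3, 81.8 in nrde-4 and 185 in glp-4, and 18137 HRDE-1 reads. A domain on chromosome V, 5470001 to 5479000, had 639 RPM in nrde-3, 80.0 in nrde-4 and 240.5 in glp-4, with 10232 HRDE-1 reads. Another on chromosome V, 15588001 to 15598000, had 563, 108 and 217 RPM, with 5121 HRDE-1 reads. A domain on chromosome IV, 9100001 to 9105000, had 60.4, 14.3 and 21.1 RPM and 72243 HRDE-1 reads. Further windows among the 10 were 8148001 to 8149000 on X, with a ratio of 23.7 (7.91 to 116), and 5978001 to 5979000 on I, with 19.6 (8.85 to 54.1). The domain around the latter, 5977001 to 5979000, held 305 HRDE-1 reads, and that from 10241001 to 10243000 on I held 61.

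The windows highest in nrde-4 lay elsewhere. Of the 10 lowest ratios of nrde-3 over nrde-4, 4 lay side by side on chromosome II from 10876001 to 10880000. The domain around them, 10874001 to 10881000, held 146 RPM in nrde-4 against 9.06 in nrde-3 and 19.2 in glp-4, so nrde-4 was 16.1 times nrde-3 (12.9 to 20.3) and 7.59 times glp-4 (6.43 to 8.99). With distinct positions nrde-4 was 12.0 times nrde-3 there (9.24 to 15.7). The domain on X from 6040001 to 6052000 was 7.55-fold higher in nrde-4 than in nrde-3 (6.36 to 9.01), and a stretch of 20 kb near the right end of chromosome I, 15034001 to 15054000, was 5.19-fold higher (4.81 to 5.60). These domains held 705, 144 and 1675 HRDE-1 reads. Those around the remaining windows of the 10 held 393 (the smg-1 target), 215, 35 and 15. The extreme windows of glp-4 rest on few molecules: its 10 highest windows over nrde-4 held 7 to 18 distinct positions in glp-4, and the 10 lowest held 0 to 3. At 4933001 to 4934000 on I, for example, glp-4 had 0 reads and nrde-4 had 119.

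In total 746 of 43690 windows tested in both pairs were at least 2-fold higher in nrde-3 than in nrde-4 and also than in glp-4. Unchanged libraries simulated with the shared nrde-3 library gave 1, and independent lists of these sizes would share 230. That simulation drew every read independently, so it leaves out copies of the same molecule, which are many in glp-4. Part of the excess may come from the shared nrde-3 library, which could not be split. With distinct positions the number was 728 of 28039, beside 10 and 226. Of the 746 windows, 42.8% held 100 or more HRDE-1 reads, against 9.89% of all windows tested.

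HRDE-1 small RNAs were mostly 22 nt long, the length of the secondary small RNAs made by RNA-dependent RNA polymerases in C. elegans. Reads of 22 nt made up 65.6% of the library, those of 21 nt 16.7% and those of 23 nt 13.5%, with Wilson intervals narrower than 0.1 percentage points. Of distinct sequences by position, 52.4% were 22 nt. The reads came from few places and from 1 strand at each. Only 36.8% of the 100265 windows of 1 kb held any read, the 10 richest windows held 5.30% of all reads, and the 500 richest held 47.9%. Of the 1429 windows with 1000 or more reads, 1388 (97.1%) had at least 90% of their reads on 1 strand. The richest was 9104001 to 9105000 on chromosome IV with 61165 reads, almost all on the plus strand. It was followed by 1698001 to 1699000 on V with 51824 reads on the plus strand and 13162001 to 13163000 on III with 46534 reads on the minus strand. Per kb, chromosomes I and II gave the most small RNAs, 13.9 and 13.6 RPM per kb, and V and X the fewest, 6.67 and 7.37, although V led in H3K9me3. Genic origin was not determined.

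Where HRDE-1 small RNAs were abundant, H3K9me3 was higher in nrde-3 than in either other strain. Among the 500 richest windows, 415 had enough ChIP reads for nrde-3 over nrde-4. Their median log2 ratio was 0.48 (0.36 to 0.57), with 284 windows above 0 and 131 below. All 10000 lists matched on density had a lower median, with a centre of -0.10. For nrde-3 over glp-4 the median was 0.52 (0.41 to 0.65; 430 windows), again above all 10000 lists. For glp-4 over nrde-4 it was -0.01 (-0.13 to 0.12; 415 windows), at percentile 0.17 of the matched lists. That position depended on how windows were counted. With distinct positions at a floor of 50 it was lost (0.17, 211 windows, percentile 35.6). It was also lost among the 1000 richest windows (0.16, 418 windows, percentile 8.35), though not among the 200 richest (-0.09, 85 windows, percentile 0.05). For the 500 richest it held at a floor of 20 (-0.01, 382 windows, percentile 1.27). The medians of nrde-3 over nrde-4 and over glp-4 stayed above all lists with distinct positions, at 0.60 and 0.68 with a floor of 50 and at 0.40 and 0.49 with a floor of 20.

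The difference grew with the number of small RNAs from 100 reads on. Relative to the median window, the median log2 ratio of nrde-3 over nrde-4 was 0.00 in windows without HRDE-1 reads and slightly lower in those with few: -0.08 (-0.11 to -0.04) with under 10 and -0.09 (-0.11 to -0.06) with 10 or more but under 100. It was 0.14 (0.09 to 0.19) with 100 or more but under 1000, 0.63 (0.57 to 0.72) with 1000 or more but under 10000, and 1.07 (0.86 to 1.40) in the 94 windows with 10000 or more. For nrde-3 over glp-4 the last of these classes reached 1.59 (1.24 to 1.87; 95 windows). For glp-4 over nrde-4 the same class was at -0.31 (-0.47 to -0.13, 92 windows). All of these classes were computed by ChIP reads only, without a check by distinct positions. They were also not matched on H3K9me3 density. Lists matched on density to the 500 richest windows had centres of -0.10 for nrde-3 over nrde-4 and -0.18 for nrde-3 over glp-4. The median windows of these pairs lay lower, at -0.40 and -0.58, so part of the height of the richer classes may go with H3K9me3 density. From the other side, 26.5% of the windows at least 2-fold higher in nrde-3 than nrde-4 held 100 or more HRDE-1 reads (24.7 to 28.3), against 8.71% of those lower (8.22 to 9.22) and 9.84% of all tested.

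**Figure D3:**
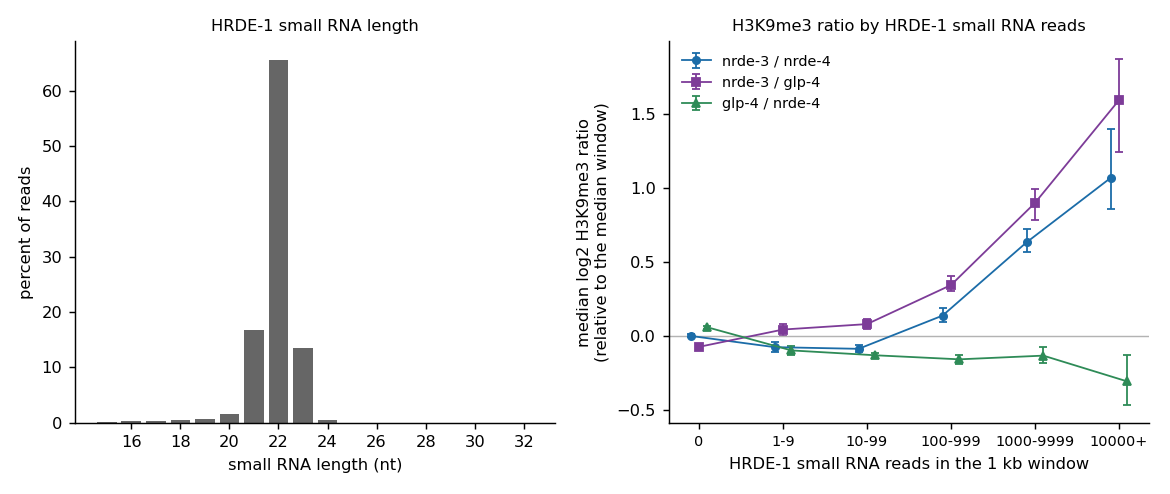
Left, percent of HRDE-1 small RNA reads (bars) by length in nt. Right, median log2 H3K9me3 ratio of 1 kb windows relative to the median window, by HRDE-1 small RNA reads in the window. Ratios are by ChIP reads, with order-statistic 95% intervals over windows, and the classes are not matched on H3K9me3 density. The ratios of nrde-3 over nrde-4 and over glp-4 reach 1.07 and 1.59 in the richest class, and glp-4 over nrde-4 is at -0.31.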

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

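The HRDE-1 library held small RNA reads inside the smg-1 RNAi target, though its labels name no RNAi treatment. It held 393 reads there (355 to 434), 18.0 times the density of the flanks (15.0 to 21.5). These were 76 distinct small RNAs, and the 180 reads of the flanks were 15, so intervals by reads are too narrow. Of the 393 reads, 18.8% were 22 nt long, against 65.6% in the whole library, and 251 were on the plus and 142 on the minus strand. A border of the target was crossed by 0 reads, and no expected number was computed.

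The comparison of distinct positions at the target and in the flanks, and that of nrde-3 with glp-4 in the flanks, were chosen after their results had been seen. The nrde-4 library is labelled as an H3K9me3 immunoprecipitation, and its reads pile up within the smg-1 target and nowhere next to it. Amplified copies of few molecules are argued against by the number of distinct positions, which per kb was 119 times that of the flanks. A candidate explanation is DNA that carries the target sequence outside its chromosomal place, such as the plasmid of the bacteria on which the worms feed. Such DNA gives no reads across the borders, and the observed number over the expected one was 0.00487 (0.000123 to 0.0272). The same value in nrde-3 was 0.694 (0.300 to 1.37), and in glp-4 too few positions lay near the borders to tell; how such DNA came through the immunoprecipitation was not tested.

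The nrde-3 library had more H3K9me3 in the smg-1 flanks than the nrde-4 library. A difference across the whole of both libraries is argued against, since 0.0301% of intervals of the same shape had as high a ratio. The intervals overlap, being taken at steps of 1 kb, so this share does not count separate places. Amplified copies are argued against as well, since the lower bound of the ratio by distinct positions was 4.86. Nuclear RNAi in the germline is a hypothesis that the values allow: nrde-3 exceeded glp-4 with a lower bound of 2.496. For this pair 0.883% of intervals of the same shape had as high a ratio by reads, and 0.214% by distinct positions. By the labels only the nrde-3 strain carries the nrde-3 mutation, so the pair does not differ in the germline alone. The hypothesis takes the glp-4 worms, kept at 23 °C by the file header, to have lacked most of the germline. Germline content was not measured here. Library series and strain cannot be told apart between nrde-3 and nrde-4 with 1 library each, the growth temperature of the nrde-3 worms is not given in the sources used here, and the absence of a library without RNAi leaves the level before RNAi open.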

How the results depend on the processing

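Of 98 alternative values, 32 stayed within the counting interval or within 1.5 times the count, 66 moved and 0 of those with an interval on 1 side of no difference changed direction; the causes were not tested. The median of HRDE-1 windows for glp-4 over nrde-4, whose interval includes 0, changed sign with distinct positions, and the balance of higher and lower windows turned for both pairs with glp-4. All listed reads, the main setting of the design, became an alternative after the data were seen. A floor of 20 distinct positions for the HRDE-1 windows was added then too and gave 0.40, -0.01 and 0.49. With distinct positions, target ratios (nrde-3 over nrde-4, glp-4 over nrde-4, nrde-3 over glp-4, the order used throughout) were 0.141, 0.0835 and 1.69, and the last 2 flank ratios 1.38 and 4.55. Windows lower in nrde-3 than nrde-4 became 1977, higher and lower in glp-4 than nrde-4 707 and 2166, and lower in nrde-3 than glp-4 689. Arms over centres became 4.64, 2.96 and 3.67 (nrde-3, nrde-4, glp-4), and medians of the HRDE-1 windows 0.60, 0.17 and 0.68. With median scaling, target ratios were 0.0575 for the first pair and 1.76 for the last, flank ratios 6.98 and 4.23, and HRDE-1 medians 0.88, -0.14 and 1.11. Window counts were 5926 and 6507 for nrde-3 over nrde-4 and 10684 and 11551 for nrde-3 over glp-4. With all listed reads, target ratios were 0.0288 for glp-4 over nrde-4 and 1.59 for nrde-3 over glp-4, and flank ratios 1.45 and 3.85. Window counts were 3825 higher and 13992 lower for glp-4 over nrde-4, and 8501 and 11899 for nrde-3 over glp-4. Arms over centres were 1.82, 1.72 and 1.77, and HRDE-1 medians 0.32, -0.38 and 0.73. Flanks of 2 kb gave 7.21, 1.47 and 4.91, and of 10 kb 2.80, 1.41 and 1.99. Windows of 2 kb gave 1054 higher and 15741 lower in nrde-3 than nrde-4, and 2240 higher and 16411 lower in nrde-3 than glp-4. For glp-4 over nrde-4 they gave 3525 higher and 6794 lower, so the balance of this pair turned there too. With a floor of 100 reads, 3200 were lower in nrde-3 than nrde-4, 3880 higher and 3514 lower in glp-4 than nrde-4, and 7038 lower in nrde-3 than glp-4. With a floor of 20 reads, 2669 were higher and 35867 lower in nrde-3 than nrde-4, and 7437 higher and 33772 lower in nrde-3 than glp-4. In glp-4 over nrde-4, 12209 were higher and 19196 lower at that floor. Arms of the outer 25% gave 5.78, 3.16 and 3.74. The 200 richest HRDE-1 windows gave -0.19 for glp-4 over nrde-4 and 0.73 for nrde-3 over glp-4. With distinct small RNAs, 52.4% were 22 nt, the top 500 windows held 22.01%, and 94.3% of the top 1000 windows had 90% on 1 strand; with 21 to 23 nt only, the top 500 windows held 48.0%. Alternatives over gene lists, exons and small RNAs with several places were not run. No paired analysis was possible because each group is 1 library. The low number of distinct molecules limits every glp-4 value.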

Other observations

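Most genes for piRNAs, small RNAs of 21 nt bound by another germline Argonaute, lie on chromosome IV. Reads of 21 nt in the HRDE-1 library did not gather there: chromosome IV held 16.5% of them and 15.9% of the 22 nt reads, for 17.4% of the total chromosome length. Small RNA density on arms over centres was 0.938 on IV, 1.05 on III, 1.44 on V, 1.74 on II, 2.19 on I and 3.27 on X. The H3K9me3 values of nrde-3 were 3.54, 4.59, 11.5, 9.02, 7.14 and 3.26, so the 2 were close on X and H3K9me3 was steeper elsewhere. Beyond the end of the ChIP listings on chromosome I, 90027 HRDE-1 reads (1.09%) were found, of which 34.4% were 22 nt.

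Sequences with several places were 50.3% of listed positions in nrde-3, 58.01% in nrde-4 and 67.8% in glp-4. In nrde-3 the listed counts sum to 178163793, of which 9597994 are reads with 1 place. A window of chromosome I, 3171001 to 3172000, chosen after its values were seen, held 14183 nrde-4 reads at 43 positions, 6007 nrde-3 reads at 39 and 11331 glp-4 reads at 34.

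H3K9me3 in windows rich in HRDE-1 small RNAs was higher in nrde-3 than in nrde-4, and the test with distinct positions took its floor of 50 after values at a floor of 20 had been seen. Scaling to the total of uniquely placed reads is argued against as the source of the sign, since with median scaling the median log2 ratio of the 500 richest windows was 0.88. That value only takes away the displacement of -0.40. The matched lists would move by the same amount, so the distance from them does not depend on scaling, and 0.88 is not a larger effect. Amplified copies are argued against as well, since with distinct positions the median was 0.60, outside the middle 95% of matched lists (0.11 to 0.24); at a floor of 20 it was 0.40, against -0.05 to 0.08. The hypothesis that H3K9me3 at these windows depends on NRDE-4 needs a median above the matched lists, and 0.48 against a range of -0.20 to -0.01 meets that need. By reads, nrde-3 was also higher than glp-4 at these windows, at 0.52. For glp-4 over nrde-4 the median was -0.01 by reads and 0.17 by distinct positions. The nrde-3 library thus exceeded both others, and its excess over nrde-4 does not single out NRDE-4. Library series remains open, since the nrde-4 library is of another series, and so does growth temperature, which is not given for nrde-3.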
